A study of Homo sapiens with 5 samples.

How the data were processed

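Total RNA from 5 samples of the HUDEP-2 cell line was sequenced, 3 labelled ERF knockout and 2 labelled wild type, the latter with titles that carry the unexplained letters SCR. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit; the strand setting of the counting is not given in the sources used here, so antisense and overlapping genes cannot be told apart from their partners. The submitters' processing notes name TopHat2 2.0.4, SAMtools, HTSeq, Cuffdiff, edgeR 2.6.12 and the human genome build hg19/GRCh37, with no roles or order. The filter and the normalization are not given in the sources used here.

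A single table was used, with the authors' comparison of wild-type and mutant cells. Its name also carries the abbreviation Pre, which no label explains, so the culture stage of the cells compared is not known. Whether the listed version of edgeR made this table of quasi-likelihood F statistics by the authors is not given in the sources used here. Per the file headers, the authors' deposited table gives a log2 fold change, a mean log2 CPM over all libraries, a quasi-likelihood F score, a p-value and an adjusted p-value per gene. It has 11979 rows: 11976 genes and 3 rows that name no gene and hold reads outside any annotated gene, reads not uniquely aligned and reads ambiguous between genes. By their log2 CPM, these 3 rows hold 21.5% of the CPM in the authors' deposited table, so the authors included them in library totals and in the adjustment of p-values. They were left out of every count and list test here. The deposited adjusted p-values were recomputed from the deposited p-values by the Benjamini-Hochberg method and differed by at most 0.676%. The table has 0 columns of values per sample, so library totals, replicate agreement, duplicate libraries and batches could not be examined, and no model was fitted again. Mean log2 CPM ran from -0.79 to 13.84 over genes, with a median of 4.64.

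The test fixed before the data were examined, for a table that holds only the authors' comparison, was used: the deposited log2 fold change with a deposited adjusted p below 0.05. The header does not name the reference group. By a rule also fixed in advance, the sign was set so that γ-globin (HBG1 and HBG2) is higher in the knockout. Of these, only HBG2 was used. Deposited values were therefore multiplied by -1. The series title states that γ-globin is reactivated when ERF is inactivated. Whether this holds for the cells compared here, whose culture stage is not known, was assumed and not tested. A standard error was derived as the absolute log2 fold change divided by the square root of F, and its 95% interval used the t distribution with 10.3 degrees of freedom, which F and p imply. Both are approximations, because the edgeR fit by the authors moderates fold changes with a prior count. The median standard error over genes was 0.07.

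This direction was checked with the F statistics. In a comparison of 3 libraries with 2, a gene of given mean and fold change has a different F depending on which group is higher. A negative binomial model of F was fitted to 1647 genes under each sign, once with equal depth in both groups and once with a free depth ratio. The log-likelihood difference was taken from the residuals of the natural logarithm of F, with genes treated as independent. The cut-offs on fold change (0.5) and expression (6 log2 CPM) were chosen after the data had been seen, from 12 settings that are all reported. On 18 simulated sets, the fit with equal depth gave the right sign in 17 and the fit with free depth in 17. Wild type was at most 1.5 times deeper in these sets, so larger depth ratios were not tested. At 1.5 times, the fit with equal depth was right in 5 of 6 sets.

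Before the data were examined, 34 gene lists with 958 entries were fixed. They cover ERF, the globin loci, fetal globin regulators, erythroid transcription factors, heme, iron, red cell and autophagy genes, other blood lineages, ETS factors, signalling responses, cell cycle, p53, interferon, antigen presentation, inflammation, stress responses, metabolism, mitochondria, ribosomes, histones, apoptosis and chromatin. A further 4 lists were written after the data had been seen and are described by counts, medians and member values, with no list test. Symbols were matched to the table, and 3 members by identifier. Lists with at least 5 measured members were tested with cameraPR of limma 3.58.1 in R 4.3.3, on the signed normal quantile of the p-value with a preset correlation of 0.01, adjusted over 29 lists. One-sided Fisher's exact tests counted called members against all other genes, adjusted over 58 tests. On 20 simulated sets of 11976 genes, a list of 30 genes shifted by 0.75 SD of the statistic was called in 14 sets and a list shifted by 1.5 SD in 20. The list test thus misses some modest shifts. Of 580 simulated lists with no shift, 1 was called. The simulated lists held genes drawn at random from shuffled values, so the rate of false calls for co-regulated genes is not known.

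Genes are named by a rule fixed before the data were examined. It takes ERF, all measured globin genes and the 12 genes with the largest change in each direction among called genes of at least 2 log2 CPM, without clone, noncoding or antisense style names. It adds up to 4 members of each list and direction with the smallest adjusted p. Genes of chromosome Y were also left out of the 12, a step that the rule did not state. Genes chosen otherwise are said to be so. Chromosomes and biotypes come from GENCODE release 29, which matched 11712 genes; it uses another genome build than the authors, so no coordinates are printed. GC content and transcript length for matched comparisons come from the same annotation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

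The alternatives were adjusted p thresholds of 0.01 and 0.1, a minimum absolute log2 fold change of 1, a minimum of 1 log2 CPM, centring on genes of at least 5 log2 CPM, and for the lists a correlation of 0.05, log2 fold changes as the statistic, ranks and 10000 random lists matched on mean expression.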

Results

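Bulk RNA-seq compared libraries labelled as HUDEP-2 cells with a knockout of ERF, an ETS-domain transcriptional repressor, with libraries labelled as wild-type HUDEP-2 cells. HUDEP-2 is an immortalised erythroid progenitor line derived from umbilical cord blood that makes mostly adult hemoglobin. The knockout group held 3 libraries and the wild-type group held 2, whose titles carry the letters SCR; the labels do not say what these stand for, so whether the wild-type cells went through a control edit is not known. The authors' deposited table gave, for 11976 genes, a log2 fold change, a mean log2 CPM over all libraries, an F statistic, a p-value and a Benjamini-Hochberg adjusted p-value. It carried no values per library, so no per-library level or SD is given and the depth of each library is unknown. Each standard error below was derived from the fold change and the F statistic of the authors' deposited table. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The 10.3 degrees of freedom that F and p imply exceed the 5 libraries, so part of this spread is shared across genes.

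The direction of the comparison was set by a rule fixed before the data were examined. The header of the authors' deposited table names no reference group, and the series title states that γ-globin is reactivated when ERF is inactivated, so the γ-globin gene HBG2 was taken as higher in the knockout. HBG2 (ENSG00000196565, chromosome 11) therefore orients the comparison and is not a finding, and it had a log2 fold change of 1.88 with a standard error of 0.22 in the authors' deposited table (adjusted p = 7.64e-05, edgeR). HBG1, its near-identical copy, was not analysed here. Reads that fit both copies fall in the class not uniquely aligned, so the HBG2 value is uncertain. The direction of every result thus rests on HBG2 alone, at a mean of 3.18 log2 CPM, below the median of 4.64 over genes.

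ERF itself (ENSG00000105722, chromosome 19) went against the knockout label under this direction. Its RNA was 1.85-fold higher in the libraries labelled knockout, a log2 fold change of 0.89 with a standard error of 0.07 and a 95% interval of 0.73 to 1.04 in the authors' deposited table (adjusted p = 6.44e-06, edgeR). Its mean expression was 5.88 log2 CPM in the authors' deposited table. RNA abundance does not measure whether an edited transcript encodes ERF protein, and the position of the edit is not given in the sources used here. With the sign read the other way, every direction below is exchanged: ERF and HBG2 are then both lower in the libraries labelled knockout. All directions are therefore given under the sign set through HBG2, which no label or header gives. Statements of higher or lower in the libraries labelled knockout assume this sign.

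The question of the comparison was which genes differ between ERF knockout and wild-type cells, with γ-globin as the gene the series is about. In the libraries labelled knockout, 28 of 29 measured integrated stress response genes were lower, with STC2, CHAC1, DDIT4 and SESN2 among the lowest. Of ERK pathway response genes 21 of 32 were higher and 4 lower, and of interferon response genes 19 of 30 were higher and 3 lower. The globins HBD, HBA1, HBA2 and HBB were higher. In the authors' deposited table, 6092 of 11976 genes (50.9%) had an adjusted p below 0.05, of which 2987 were higher and 3105 lower in the libraries labelled knockout. This split depends on the setting: it was 2566 higher and 3532 lower after centring on genes of at least 5 log2 CPM, and 1689 higher and 1296 lower over those genes alone, a setting chosen after the data had been seen. Most changes were small, with a median absolute log2 fold change of 0.36 among called genes, and 93.6% of the calls were under 2-fold. Among called genes changed at least 2-fold, 121 were higher and 271 lower. At an unadjusted p below 0.05, 6843 genes passed.

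**Figure D1:**
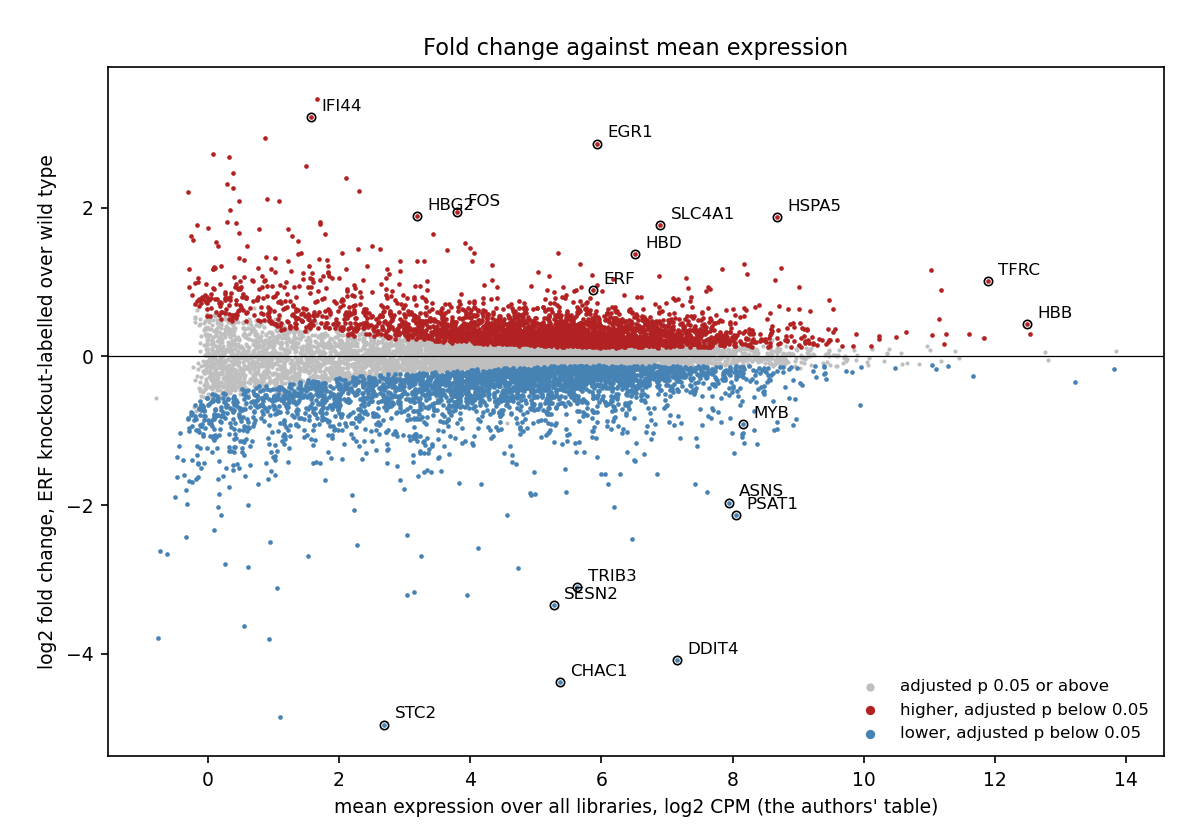
Each point is a gene of the authors' deposited table, with the mean expression over all libraries in log2 CPM on the x axis and the log2 fold change of the libraries labelled knockout over wild type on the y axis; red and blue mark the 2987 higher and 3105 lower genes with an adjusted p below 0.05. STC2, CHAC1 and DDIT4 lie below -4, EGR1 lies at 2.86, and the labelled genes IFI44 and ASNS were picked for display after their values were seen.

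Of the 12 genes with the largest decreases among those named by the fixed rule, 8 were on the integrated stress response list; ADM2, GPT2, ASS1 and TSC22D3 were not. STC2, a secreted glycoprotein, had the lowest log2 fold change of the named genes, -4.95 with a standard error of 0.21 (adjusted p = 8.86e-08, edgeR) in the authors' deposited table. CHAC1, which degrades glutathione, followed at -4.38 with a standard error of 0.07 (20.8-fold lower, adjusted p = 1.13e-10) in the authors' deposited table. DDIT4, an inhibitor of mTORC1 signalling, stood at -4.09 with a standard error of 0.11 (17.0-fold lower) in the authors' deposited table. SESN2, a leucine sensor, stood at -3.35, and CTH, an enzyme of cysteine synthesis, at -3.21 in the authors' deposited table. The authors' deposited table gave -3.21 for ADM2, -3.17 for ATF3, -3.10 for the pseudokinase TRIB3 and -2.85 for the transaminase GPT2. The remaining 3 of these 12 genes were ASS1 (-2.68), TSC22D3 (-2.58) and PHGDH (-2.54), an enzyme of serine synthesis, in the authors' deposited table.

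As a group, 28 of the 29 measured genes of the integrated stress response, the programme that ATF4 drives when amino acids are short or translation initiation is blocked, were lower. None was higher, and the remaining member, PPP1R15A, was not past the threshold, with a log2 fold change of -0.09 in the authors' deposited table. The median of the group was -1.85 (cameraPR, preset correlation 0.01, adjusted p = 6.53e-25), and its enrichment among lower genes had an adjusted p of 4.44e-14 (Fisher's exact test, one-sided). ATF4 RNA itself was 1.84-fold lower, at -0.88 with a standard error of 0.05 in the authors' deposited table (adjusted p = 3.90e-07). PSAT1, a further enzyme of serine synthesis, stood at -2.14 in the authors' deposited table. NUPR1 (-3.80) and ALDH1L2 (-3.63), chosen after their values were seen, lay below SESN2 in the authors' deposited table. Adjusted over the list alone, the count was again 28 lower and 0 higher.

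Genes that respond to the ERK pathway, which phosphorylates ERF and keeps it out of the nucleus, were mostly higher. Of 32 measured, 21 were higher, 4 lower and 7 not past the threshold, with a median of 0.53 (cameraPR adjusted p = 8.50e-06), and the counts adjusted over the list alone were identical. EGR1, an immediate early transcription factor, was 7.27-fold higher, at 2.86 with a standard error of 0.14 in the authors' deposited table (adjusted p = 2.17e-07). FOSB stood at 2.22, FOS at 1.95 and JUNB at 0.93 in the authors' deposited table. The phosphatases DUSP2 and DUSP1, which act against MAP kinases, stood at 1.64 and 1.53, and the cyclin CCND1 at 1.24 in the authors' deposited table. The 4 lower members were ATF3, which is also a stress response gene, PLAUR (-0.56), KLF10 (-0.25) and IER5 (-0.19). The 7 not past the threshold were DUSP6, SPRY2 and ETV5 (each 0.14), IER2 and SPRED2 (each 0.08), MYC (0.07) and SPRED1 (0.04). No contrast separates genotype from culture state, so these changes cannot be ascribed to loss of ERF. Within the ETS family to which ERF belongs, 5 of 15 measured members were higher and 1 lower (cameraPR adjusted p = 0.307), or 5 and 0 adjusted over the list alone. The 5 higher members include ERF itself (0.89). ELK3 (0.59), ELK1 (0.35) and ETS2 (0.22) were also among those higher, and ETV3, of the same subfamily as ERF, stood at -0.16 in the authors' deposited table.

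Globin genes were higher beyond the gene that set the direction. HBD, the δ-globin gene next to HBB on chromosome 11, was 2.59-fold higher, at 1.37 with a standard error of 0.15 in the authors' deposited table (adjusted p = 5.06e-05). HBB, the adult β-globin gene and among the most abundant RNAs at 12.48 log2 CPM, was 1.35-fold higher, at 0.43 with a standard error of 0.10 in the authors' deposited table (adjusted p = 0.00588). On chromosome 16, HBA1 stood at 0.75 and HBA2 at 1.06 in the authors' deposited table, but these copies are near-identical and reads that fit both were not counted, so their split is uncertain. HBM, at 0.34, was also higher, whereas HBQ1, at -0.07, was not past the threshold in the authors' deposited table. Mean expression of HBG2 was 3.18 log2 CPM against 6.51 for HBD and 12.48 for HBB in the authors' deposited table. Of the 3 measured genes of the β-globin list, HBG2 was higher by the rule that set the direction, and HBB and HBD were higher as well; 3 of the 4 of the α-globin list were higher. Adjusted over the list alone, these counts were identical. HBE1, HBBP1 and HBZ were not analysed here.

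**Figure D2:**
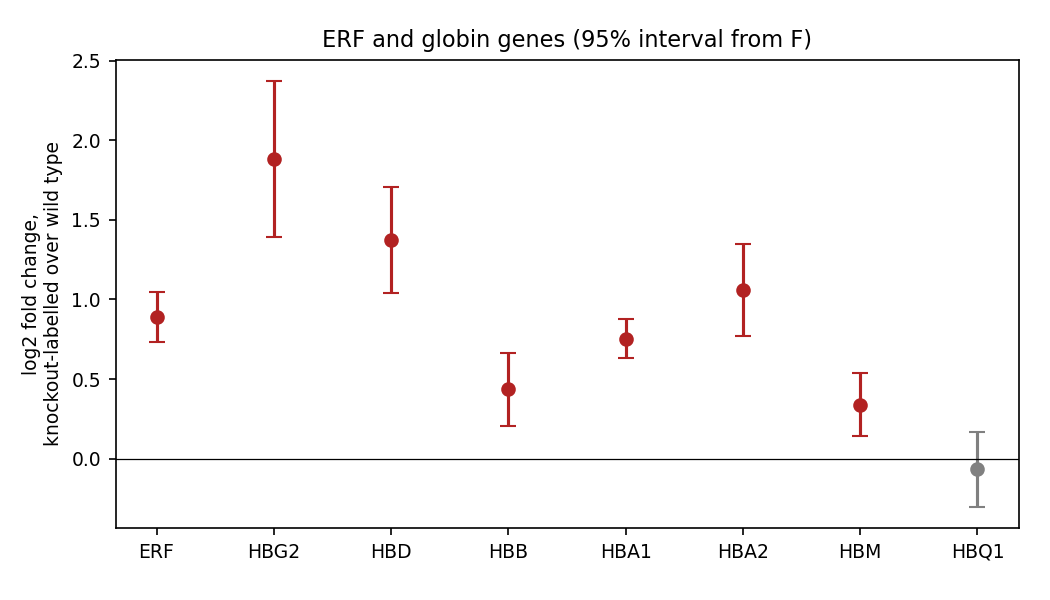
Points give the log2 fold change of the libraries labelled knockout over wild type for ERF and the globin genes of the authors' deposited table, and bars give the 95% interval derived from F. All intervals lie above 0 except that of HBQ1, which runs from -0.30 to 0.17.

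Known regulators of fetal globin moved in both directions. Of 33 measured, 11 were higher, 8 lower and 14 not past the threshold, with a median of 0.02, a mean of -0.02 and no call for the list (cameraPR direction lower, adjusted p = 0.969). BCL11A, a repressor of γ-globin, was 1.44-fold lower, at -0.53 with a standard error of 0.05 in the authors' deposited table (adjusted p = 2.10e-05). MYB, a progenitor transcription factor, stood at -0.91, and RCOR1, a corepressor subunit, at -0.87 in the authors' deposited table. Among the higher genes were the nuclear receptor NR2F2 (0.79), PRMT5 (0.40) and the deacetylase HDAC1 (0.31) in the authors' deposited table. Further regulators were chosen after their values were seen. LIN28B, a fetal RNA-binding protein at a low 0.83 log2 CPM, stood at 1.08, and IGF2BP1, a further fetal RNA-binding protein, at -0.78 in the authors' deposited table. KLF1 (0.17), an activator of adult globin, and ZBTB7A (0.16), a repressor of γ-globin, were higher by small amounts in the authors' deposited table.

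The erythroid programme as a whole showed no shift that the list tests called. Of 25 erythroid transcription factors, 7 were higher and 9 lower (cameraPR adjusted p = 0.634). GATA2, a factor of early progenitors, was 1.90-fold higher at 0.93, and HES6 was lower at -1.11 in the authors' deposited table. GATA1, the master factor of erythroid cells and chosen after its value was seen, had a log2 fold change of -0.12 (adjusted p = 0.103) in the authors' deposited table. Of 35 red cell membrane and late erythroid genes, 11 were higher and 9 lower (adjusted p = 0.601). SLC4A1, the anion exchanger band 3, was 3.41-fold higher, at 1.77 with a standard error of 0.14 in the authors' deposited table. DMTN stood at 0.55, the glycophorin gene GYPE at -0.51 and GYPB at -0.40 in the authors' deposited table, and the glycophorins share sequence, so their values are uncertain. In heme synthesis, 4 of 20 genes were higher and 9 lower (adjusted p = 0.549), with ALAS2 at 0.22 and ALAD at -0.56 in the authors' deposited table. Of 17 iron handling genes, 3 were higher and 4 lower, with a positive median of 0.04 and mean of 0.02 although the test pointed lower (adjusted p = 0.969). TFRC, the transferrin receptor, was 2.02-fold higher at 11.89 log2 CPM in the authors' deposited table.

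Endoplasmic reticulum stress genes parted in direction. Of 22 unfolded protein response genes, 14 were higher, 5 lower and 3 not past the threshold, with a median of 0.38 (cameraPR adjusted p = 0.0167), and the counts adjusted over the list alone were identical. With a correlation of 0.05 in place of 0.01, this call was lost (adjusted p = 0.119). The higher members named here are chaperones: HSPA5 was 3.66-fold higher, at 1.87 with a standard error of 0.07, HSP90B1 stood at 1.19, PDIA4 at 0.88 and CALR at 0.75 in the authors' deposited table. The lower members include XBP1 (-0.93) and ATF6 (-0.29), transcription factors of this response, and HERPUD1 (-1.09) and EDEM1 (-0.53), which act in protein degradation, in the authors' deposited table. HSPA1A, a heat-inducible cytosolic chaperone with a near-identical copy, stood at 2.39 in the authors' deposited table.

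Interferon-stimulated genes were mostly higher. Of 30 measured, 19 were higher, 3 lower and 8 not past the threshold, with a median of 0.38 (cameraPR adjusted p = 0.000107), and 20 and 3 when adjusted over the list alone. The antiviral genes IFIT3 (1.46), ISG15 (1.44), IFIT1 (1.43), IFIT2 (1.39) and RSAD2 (1.39) were between 2.63-fold and 2.76-fold higher in the authors' deposited table. IRF1 (-0.45), DDX58 (-0.26) and STAT2 (-0.20) were lower in the authors' deposited table. Of 12 NF-kB and inflammatory genes, 9 were higher and 1 lower, with a median of 0.51 (cameraPR adjusted p = 0.0152), in counts identical to those adjusted over the list alone. This call was lost with a correlation of 0.05 (adjusted p = 0.0646). It held narrowly with a minimum of 1 log2 CPM (cameraPR adjusted p = 0.0477). IL8, which lay below 2 log2 CPM, stood at 2.31 and IER3 at 1.31 in the authors' deposited table. The lower gene, TNFAIP3, stood at -1.18 there. Antigen presentation genes had 5 of 13 higher and 2 lower (adjusted p = 0.601), with HLA-B at 1.17 and PSMB9 at -1.06 in the authors' deposited table.

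In the cell cycle, genes of the G2 and M phases leaned higher by small amounts. Of 37 measured, 20 were higher, 3 lower and 14 not past the threshold, with a median of 0.15 (cameraPR adjusted p = 0.00198), and 20 and 5 when adjusted over the list alone. This call was lost with a correlation of 0.05 (adjusted p = 0.0646) and with log2 fold changes in place of z values (adjusted p = 0.0915). CDC20 stood at 0.52, BIRC5 at 0.52 and PTTG1 at 0.47 in the authors' deposited table. Of 36 G1/S genes, 9 were higher and 13 lower (adjusted p = 0.969), with CCNE2 at 0.78 and the licensing factor CDT1 at -1.03 in the authors' deposited table. CDK inhibitors and p53 targets had 9 of 29 higher and 7 lower, with a median of 0.08 and a mean of -0.02 (adjusted p = 0.810). CDKN1A, a CDK inhibitor at 0.33 log2 CPM, was 6.40-fold higher, at 2.68 with a standard error of 0.26 in the authors' deposited table.

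**Figure D3:**
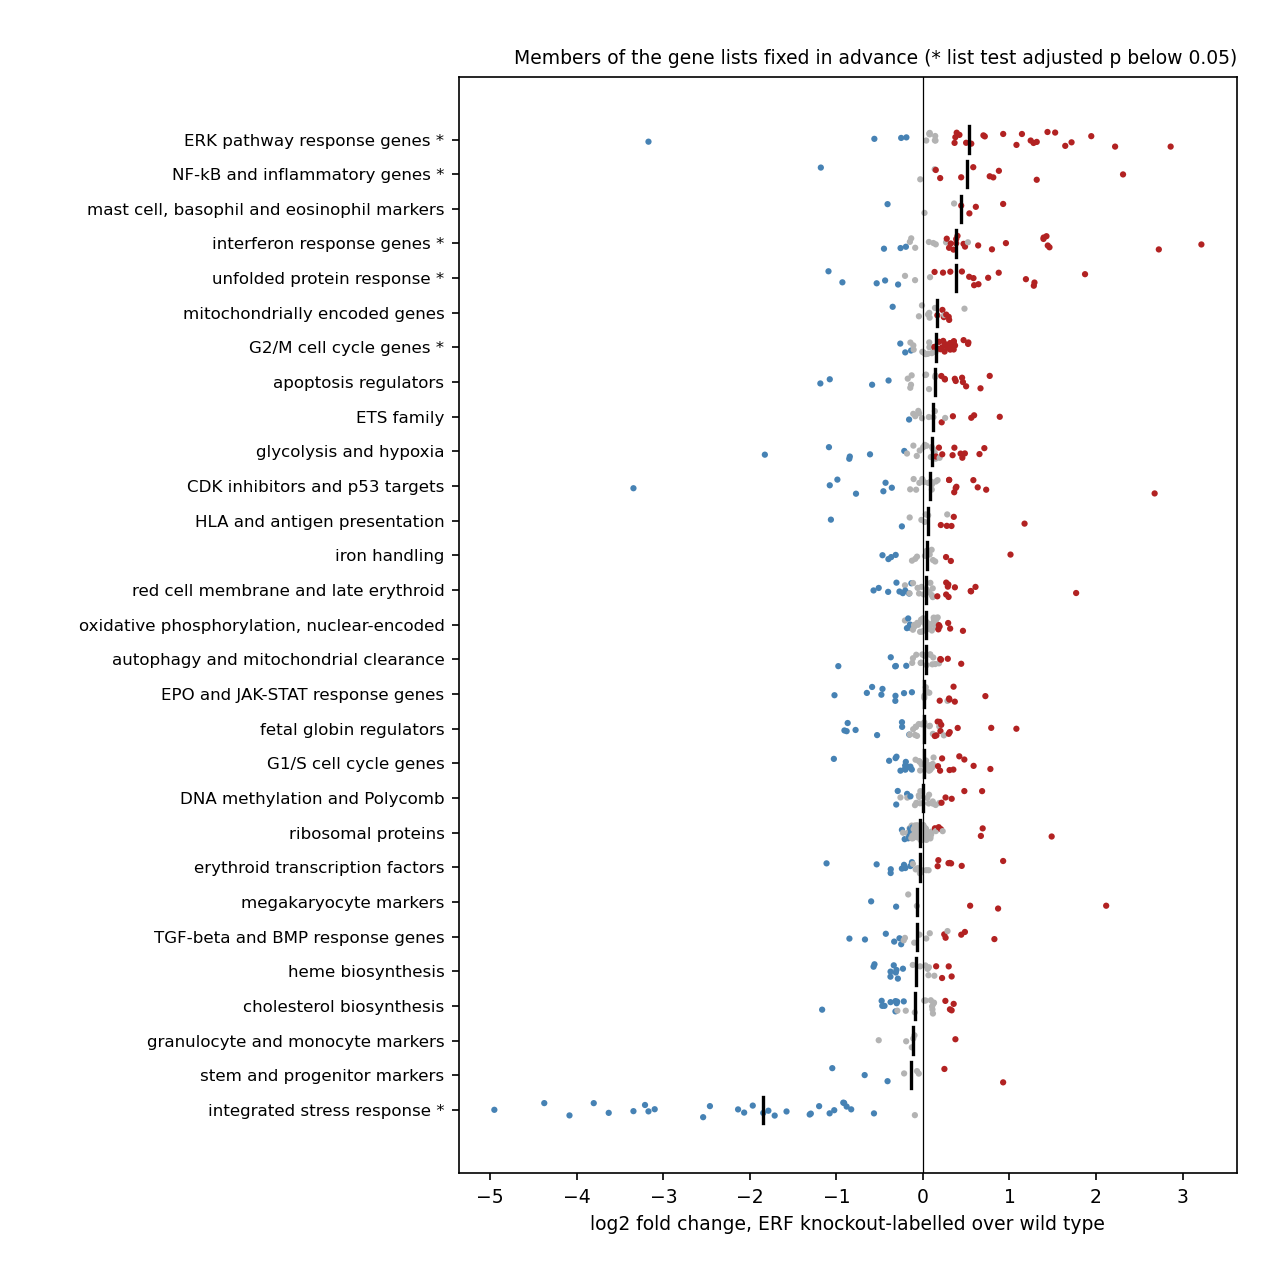
Each point is a measured member of a gene list fixed before the data were examined, at its log2 fold change of the libraries labelled knockout over wild type in the authors' deposited table; red is higher, blue lower and grey not past an adjusted p of 0.05, and the black bar is the median. Lists with an asterisk had a list test adjusted p below 0.05, with medians from -1.85 for the integrated stress response to 0.53 for ERK pathway response genes.

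Markers of other blood lineages were measured for few genes each. Of 7 mast cell, basophil and eosinophil markers, 4 were higher and 1 lower, with a median of 0.44 (cameraPR adjusted p = 0.192, and adjusted p = 0.0029 against random lists matched on mean expression). The tryptase genes TPSAB1 (0.61) and TPSB2 (0.54) share reads, and they were higher while KIT stood at -0.41 in the authors' deposited table. Megakaryocyte markers had 3 of 7 higher and 2 lower, with a median of -0.07, a mean of 0.34 and a test pointing higher (adjusted p = 0.763), and RAB27B stood at 2.12 at 0.90 log2 CPM in the authors' deposited table. Granulocyte and monocyte markers had 1 of 6 higher and 0 lower (adjusted p = 0.763). Stem and progenitor markers had 2 of 8 higher and 3 lower (adjusted p = 0.587). The lymphoid marker measured, IL2RB, had a log2 fold change of 0.19 that was not past the threshold in the authors' deposited table.

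Of the 34 fixed lists, 29 had at least 5 measured members and were tested, and cameraPR called 6 of them: the integrated stress response as lower, and ERK response, interferon, G2/M, NF-kB and unfolded protein response genes as higher. The other 23 had adjusted p-values from 0.192 to 0.969. An estimated correlation between genes needs library values, so these calls were not tried with one; with a preset correlation of 0.05 the first 3 of them held, at adjusted p-values of 2.24e-13, 0.00492 and 0.0137. In 25 of the 34 lists the counts adjusted over the list alone equalled those adjusted over all genes.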

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

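Of the tests below, those of expression floor noise, of the tRNA synthetases, of culture state, of the sign with equal depth and of the matched noncoding genes were chosen only after the result was seen.

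Reads that were counted to no gene make up a part of the authors' deposited table that no gene comparison uses, and they were singled out because they carry signal outside the main measurement. By mean CPM, 7.843% of reads lay outside any annotated gene, 5.455% were not uniquely aligned and 8.178% were ambiguous between genes. The first of these differed between the groups in the authors' deposited table, with a log2 fold change of -0.17 in the libraries labelled knockout (adjusted p = 0.0117), and the others were not past the threshold, at 0.05 and 0.03.

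ERF RNA was 1.85-fold higher in the libraries labelled knockout, against what a label of knockout leads a reader to look for. A shift of its surroundings is argued against, since the 20 nearest measured coding genes on chromosome 19 had a median of 0.0246 with quartiles of -0.11 and 0.23, although the highest of them, at 1.04, lay above ERF. A reversed sign with libraries of equal depth is also argued against, though by a small margin of fit. The residual SD of the natural logarithm of F was 0.367 for the sign used and 0.392 for the opposite sign. The log-likelihood difference was 107.842 in favour of the sign used. It ran from 30.2 to 121 over 12 settings, and from 2.73 to 43.6 when the model had a term for the sign of the fold change. It treats genes measured in the same 5 libraries as independent, so its size can overstate the evidence. With the depth ratio free, however, the difference was -8.856, in favour of the opposite sign. It ran from -8.856 to 2.03 over the same settings, of which 8 favoured the opposite sign and 4 the sign used. This fit found the right sign in 17 of 18 simulated sets. Wild type was at most 1.5 times deeper in those sets, so they do not test the larger ratios at issue. A reversed sign with wild-type libraries 2.53 to 3.99 times deeper therefore stays open, and no library depth is known that would decide it. The direction in all parts of the text thus rests on the series title, and a frameshift that leaves or raises ERF RNA may explain the value but was not tested.

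Integrated stress response genes were lower in the libraries labelled knockout, with a median of -1.85 over 29 genes. Base composition and length are argued against, since 0% of 10000 random lists matched on GC content, transcript length and mean expression had a median as low, and the lowest was -0.23. Noise of weakly expressed genes is argued against as well, since the 20 members of at least 5 log2 CPM had a median of -1.30. Lower ATF4 output stays open: cytosolic tRNA synthetases, some of which ATF4 drives, lay below the mitochondrial ones by -0.57 in median, and by -0.33 without the 4 on the stress list, but these lists were written after the data had been seen, lower ATF4 targets are the pattern itself, and RARS (0.53) and FARSA (0.27) were higher in the authors' deposited table. Loss of ERF and a difference in culture state, such as amino acid supply or cell density at harvest, cannot be told apart, since 0 contrasts separate genotype from culture.

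Weakly expressed and noncoding genes leaned lower in the libraries labelled knockout, though most were not past the threshold: of 1179 genes up to 1 log2 CPM, with a median of -0.12, 153 were higher and 279 lower, and of 677 noncoding genes, with a median of -0.18, 71 were higher and 212 lower. The 1250 genes above 7 log2 CPM had a median of 0.04. For the noncoding genes, base composition and length are argued against. With mean expression fixed, the slope on noncoding status kept 107% of its size (95% bootstrap interval 99.5 to 118) once both entered. Whether base composition and length explain the trend with mean expression was not tested. In 100% of 10000 draws, coding genes matched on mean expression had a median above that of the noncoding genes, which describes the pattern and tests no cause. More unspliced or intergenic RNA in the wild-type libraries and a biological change in noncoding transcription cannot be told apart, since both would give these values and the lower share of reads outside annotated genes.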

How the results depend on the processing

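The choices made only after the data had been seen were leaving out the rows that name no gene with a new adjustment, reading the sign the other way, keeping only genes of at least 5 log2 CPM, and leaving members of the stress response list out of other lists. No paired analysis was possible because the table holds no values per library; for the same reason DESeq2 size factors, a fit without a count filter, another pseudocount, leaving out each library and an estimated correlation between genes were not run. The count of 6092 genes became 4299 at an adjusted p of 0.01, 7020 at 0.1, 5702 with a minimum of 1 log2 CPM and 6098 after centring, which lowered the share of higher calls from 49.0% to 42.1%. It was 6092 with the rows naming no gene left out. It fell to 392 (121 higher, 271 lower) with a minimum absolute log2 fold change of 1, since most changes are smaller. It fell to 2985 (1689 higher, 1296 lower) over genes of at least 5 log2 CPM, where fewer genes were tested. The sign read the other way exchanges the counts to 3105 higher and 2987 lower. All 31 named ERF, globin and top genes stayed on their side of the threshold and in their direction with centring and with the minimum of 1 log2 CPM.

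Of 29 lists, 6 were called, and 6 with ranks and without members shared with the stress response list. With the minimum of 1 log2 CPM, 28 lists could be tested and 6 were called. With a correlation of 0.05, 3 were called. Unfolded protein response, NF-kB and G2/M genes were then not past the threshold, so these 3 calls depend on the assumed correlation. With log2 fold changes as the statistic, 5 were called, G2/M genes being lost; that cause was not tested. Against matched random lists 8 were called, with ribosomal proteins (adjusted p = 0.0348) and mast cell markers (adjusted p = 0.0029) added. No list changed direction past the threshold. Enrichment called 6 lists at adjusted p thresholds of 0.05 and 0.01 and with the minimum of 1 log2 CPM. Depth per library is unknown. With the sign used, a fit to the F statistics with equal depth put it at 33.5 M reads, with a coefficient of variation between libraries of 4.08%. With the opposite sign and a free depth ratio, the fit gave 42.4 M reads per knockout library and wild type 2.53 times deeper. These are model values and not measurements. Weak genes were less precise, so a missing call there is not evidence of no change.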

Other observations

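The 4 lists in the first paragraph were written only after the data had been seen, so their counts and medians describe what was noticed and no list test is given. Cytosolic tRNA synthetases were lower in 14 of 20 genes and higher in 2, with a median of -0.54, and WARS (-1.30) and CARS (-1.28) were among the lower and RARS (0.53) and FARSA (0.27) were the higher ones in the authors' deposited table. Their mitochondrial counterparts had 6 of 16 higher and 3 lower, with a median of 0.03. Of 17 amino acid transporters, 11 were lower and 6 higher; every one of these 17 is a called gene, so the list is no sample of such transporters. SLC38A1 stood at -3.12, SLC7A11 at -2.46 and SLC1A4 at -2.13, whereas SLC7A6 stood at 0.73 in the authors' deposited table. Heat shock chaperones and their cofactors were higher in 24 of 31 and lower in 2, with a median of 0.56, among them HSPH1 (1.18), HSPA8 (1.16) and DNAJA1 (1.11), while HSPA13 stood at -1.41 in the authors' deposited table.

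Other lists fixed in advance were not called as groups, though single members changed. Glycolysis and hypoxia genes had 10 of 29 higher and 6 lower, with a median of 0.10 and a mean of -0.03 (adjusted p = 0.601), with LDHA at 0.45 against VEGFA at -1.83 and PDK1 at -1.09 in the authors' deposited table. Cholesterol synthesis had 4 of 25 higher and 10 lower (adjusted p = 0.587). Apoptosis regulators had 10 of 23 higher and 4 lower (adjusted p = 0.549), with MCL1 at 0.50 and the BH3-only genes PMAIP1 and BBC3 at -1.19 and -1.08 in the authors' deposited table. Responses to erythropoietin and JAK-STAT signalling had 6 of 21 higher and 9 lower, with a median of 0.02 and a mean of -0.07 (adjusted p = 0.710), with CCND3 at 0.72, JAK2 at -0.65 and SH2B3 at -1.02 in the authors' deposited table. TGF-beta and BMP response genes had 5 of 18 higher and 6 lower (adjusted p = 0.810), with BMPR2 at -0.85 and SKIL at 0.83 in the authors' deposited table.

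Of 72 ribosomal proteins, 58 were not past the threshold, 6 were higher and 8 lower, with a median of -0.03 and a mean of 0.00. The list was not called by cameraPR (adjusted p = 0.634) but was called as lower against random lists matched on mean expression (adjusted p = 0.0348). Adjusted over the list alone, 3 were higher and 2 lower. RPS10 (1.49), RPL26 (0.69) and RPS26 (0.67) stood apart in the authors' deposited table, and ribosomal genes have many processed copies, so these values are uncertain. RPS10 was not among the 12 named largest increases, so it was not past the threshold or lay below 2 log2 CPM. Nuclear genes of oxidative phosphorylation had 6 of 41 higher and 4 lower (adjusted p = 0.587). Mitochondrially encoded genes had 6 of 15 higher and 1 lower, with a median of 0.17 (adjusted p = 0.194). Autophagy and mitochondrial clearance genes had 4 of 24 higher and 5 lower, with a median of 0.03 and a mean of -0.02 (adjusted p = 0.969), with CALCOCO2 at -0.98 in the authors' deposited table. DNA methylation and Polycomb genes had 5 of 25 higher and 4 lower, with a median of -0.00 and a mean of 0.04 (adjusted p = 0.663), with CBX2 at 0.68 and UHRF1 at 0.48 in the authors' deposited table. Of 4 measured replication-dependent histone genes, 3 were higher, with a median of 0.67 and HIST1H1C at 1.03 in the authors' deposited table, too few for a list test.

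Within the interferon list, the 2 measured genes with the largest standard errors were weakly expressed. IFI44, chosen after its value was seen, stood at 3.22 with a standard error of 0.52 at 1.57 log2 CPM, and OASL, chosen likewise, at 2.73 with a standard error of 0.28 at 0.08 log2 CPM in the authors' deposited table. Among chromosomes 1 to 22 and X, none stood apart as a whole. Medians of coding genes of at least 4 log2 CPM ran from -0.06 on chromosome 18 to 0.07 on chromosome 19.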
